A study of Mus musculus with 16 samples.

How the data were processed

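The series holds RNA sequencing of mouse myeloid sarcomas and leukaemia-infiltrated whole bone marrow. Per the labels' protocols, tumours were freed of surrounding tissue and placed straight into Trizol, whereas marrow was crushed from leg and pelvic bones, filtered and cleared of red cells before Trizol, so handling and tissue went together. Per the labels' protocols, spike-in RNA was added, poly(A) RNA was selected and libraries were made with an NEBNext kit. The authors deposited 1 table of whole-number counts per gene symbol, with 23999 symbols and 16 libraries, and its values are raw counts that sum to a different total in each library. STAR, DESeq and DESeq2 and the mm9 build are named per the submitters' processing notes, without versions or roles. Strand settings and the gene annotation used for counting are not given in the sources used here. Every column was mapped to a sample by its name, 0 columns belonged to other samples, and 0 rows lacked a gene name. The table held 0 spike-in rows, and 2844 symbols had no count in any library.

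Libraries of the same mouse and tissue were summed, which gave 14 samples of 1 mouse and tissue each: 4 SMC3+/- sarcoma mice, 9 SMC3+/- marrow mice and 1 sarcoma labelled SMC3 wild type. The label 1268_1270 may name 1 mouse or 2 pooled mice and was treated as 1 mouse, so the count of 4 sarcoma mice rests on that reading. No pair of libraries matched within sampling noise, and the closest, the 2 tumours of mouse 2721, had a mean chi-square per gene of 18.6. Counts were scaled by TMM and filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3, and groups were compared with the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest). Calls required a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided unless stated. Levels are CPM on TMM-scaled totals of the deposited counts, and list means are log2 CPM with a prior count of 2. The SE given with an edgeR fold change is the absolute log2 fold change divided by the square root of its F statistic. It is thus back-calculated from the test and approximate, above all for genes with marrow counts near 0. The counts carry no molecular identifiers, so intervals and floors cover counting error only, and a count of 0 over the 9 marrow samples allows up to 3 counts, or 0.0146 CPM.

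The 38 gene lists were fixed before the data were examined and were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 38 lists. Camera with an estimated correlation and fry were run beside it. Measured members are those that passed the count filter, such as 4 of 11 lymphoid stroma, 4 of 13 liver and 8 of 17 epithelium and skin genes. A gene near 0 in marrow passes it only through the sarcomas, so the share called higher in such lists is partly preset. The tumour labelled SMC3 wild type was compared with the 4 SMC3+/- sarcoma mice under the assumption that it varies as they do, and list medians were ranked among 10000 random lists of the same size matched on expression, which describes these libraries and tests nothing. Similarity of tumours, and of both tissues, of the same mouse was tested by exact permutation. Mice 1267 and 2721 gave both tissues per the labels, so the mouse pairs samples. Within tissue, the correlation of same-mouse deviations was 0.29 for mouse 1267 and 0.21 for mouse 2721.

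Genes named in the text were chosen by a rule written before the data were examined. It took the cohesin genes and Npm1, the 8 genes with the largest positive and the 8 with the largest negative fold change among called genes with an average log2 CPM of at least 3 and no overlap of the groups, up to 4 members per list with the smallest adjusted p, and the 6 genes furthest above and below the SMC3+/- range in the lone tumour, again at an average log2 CPM of at least 3. Predicted genes were counted and not named, and the text reports part of the other genes that met the rule, picked after their values were seen. For the negative direction 4 genes met the rule.

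Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, 4 other scalings, 2 other count filters, removal of haemoglobin and muscle genes, tumour libraries as units, a mouse random effect, the first tumour alone, 2 fits with the mouse as a block, no mouse in both tissues, the lone tumour added, no robust estimation, and each mouse left out in turn. Removal of libraries with few long transcripts and offsets for transcript length and GC content were added after the data were seen. Transcript lengths and GC content came from the GENCODE mouse annotation on a later build than mm9 and were matched by symbol only. Of 9560 genes with a mean log2 CPM of at least 3, 99.3% had a length.

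On simulated counts with 200 changed genes, the tissue comparison over 14216 genes called 117, with 5 false calls, and recovered 30 of 100 genes changed 4-fold and 82 of 100 changed 16-fold. The comparison of 1 tumour with 4 mice recovered 0 of 200 over 16878 genes. The changed genes had an average log2 CPM of at least 3. Simulated counts were independent between samples and genes, with no loss of long transcripts and no sample set apart. These rates therefore hold for that setting and do not give the false calls in the real libraries.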

Results

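RNA was sequenced from myeloid sarcomas, solid tumours of acute myeloid leukaemia cells outside the marrow, and from leukaemia-infiltrated whole bone marrow of mice with mutant NPM1 (NPM1cA). Sarcomas of 4 SMC3+/- mice were measured, mouse 948 and mouse 2721 with 2 tumours each (1268_1270 counted as 1 mouse, although its label may name 2 pooled mice), beside marrow of 9 SMC3+/- mice and 1 sarcoma, of mouse 841, labelled SMC3 wild type. Mice 1267 and 2721 gave both tissues. The libraries held 12395041 to 39197660 counts in marrow, 12072482 to 33605464 in the SMC3+/- sarcomas and 9797201 in mouse 841. In 4 libraries transcripts longer than 6 kb were low against the median library. Their median log2 deviation was -2.23 in marrow 737, -2.30 in marrow 779, -2.04 in marrow 782 and -1.21 in tumour 1 of mouse 948, and it lay between -0.93 and 0.62 in the other 12.

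**Figure D1:**
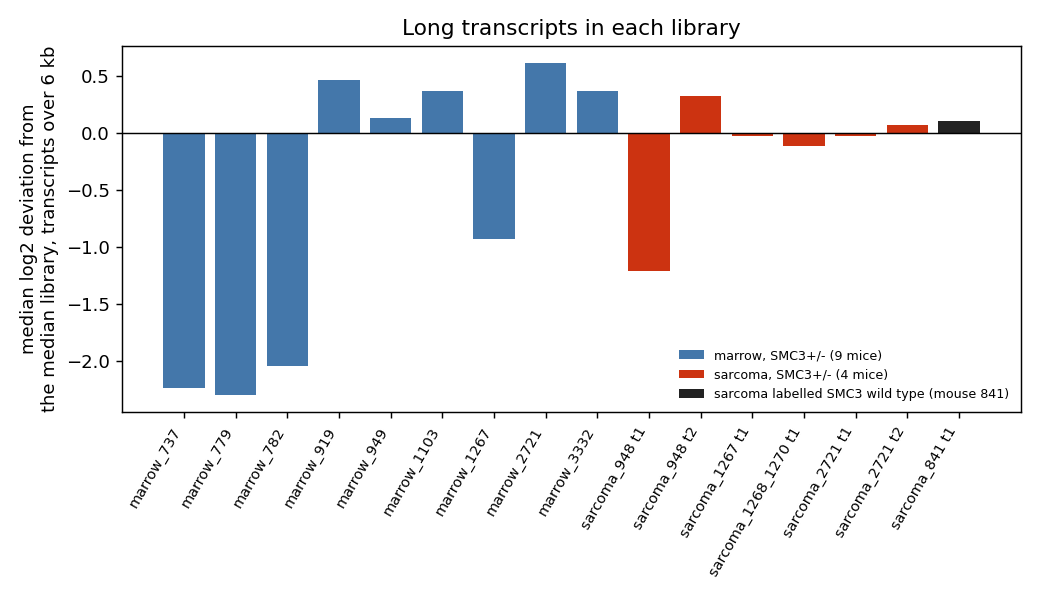
Median log2 deviation of transcripts longer than 6 kb from the median library, with 1 bar per library and bars starting at 0. The bars of marrow 737, 779 and 782 reach -2.23, -2.30 and -2.04, and that of tumour 1 of mouse 948 reaches -1.21.

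Smc3 encodes a core subunit of cohesin, the ring complex that holds sister chromatids together and shapes chromatin loops, and was read in every sample as a check of the labels. Its level was 137 CPM in the sarcoma labelled SMC3 wild type, inside the 63.6 to 217 CPM of the 4 SMC3+/- sarcomas, of which 2 were higher. The difference of 0.15 log2 units was smaller than the SD of 0.83 between the SMC3+/- mice, and scaling to pan-leukocyte genes turned it to -0.74, with an SD of 1.31. The Smc3 level therefore did not separate the genotypes, and the labels do not say which part of the gene is altered. In marrow Smc3 reached 136 to 233 CPM in 6 mice but 5.48, 3.53 and 8.46 CPM in mice 737, 779 and 782, the marrow libraries low in long transcripts. This fall was not particular to Smc3. In those mice Smc1a had 5.64, 0.558 and 3.75 CPM and Nipbl 6.69, 5.765 and 7.36 CPM, against at least 95.65 and 88.36 CPM in the other 6. Not every cohesin gene fell: Rad21 had 180, 137 and 220 CPM there and Cdca5 89.1, 48.9 and 105 CPM. Npm1, a nucleolar chaperone, had 178 to 762 CPM in marrow, 151 to 717 CPM in SMC3+/- sarcomas and 660 CPM in mouse 841. The cohesin subunits Rad21 (211 ± 54.8 CPM in 4 sarcomas, 227 ± 52.5 CPM in 9 marrows, mean ± SD) and Stag2 (217 ± 69.2 against 213 ± 39.6 CPM) did not pass the test between tissues. None of 15 measured cohesin genes was called, 0 also when adjusted over the list alone (camera adjusted p = 0.286, adjusted p = 0.839 with an estimated correlation). Without the 4 libraries low in long transcripts camera called the list lower in sarcomas (adjusted p = 0.000918, range over alternatives 0.000133 to 0.952), again with 0 members called, and its median of -0.13 over all libraries turned to 1.53 with pan-leukocyte scaling.

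What sets sarcoma apart from infiltrated marrow was asked in the SMC3+/- mice. Ctsl, a lysosomal cysteine protease, rose by 3.60 ± 0.33 (log2, SE back-calculated from the F statistic), from 58.7 ± 23.7 CPM in 9 marrows to 744 ± 157 CPM in 4 sarcomas (edgeR adjusted p = 0.000144). C1qa and C1qc, complement genes of tissue macrophages, rose by 4.76 ± 0.91 (adjusted p = 0.00719) and 4.55 ± 0.86 (adjusted p = 0.00683), to 174 ± 46.3 and 168 ± 41.3 CPM. C1qa lost the call without the 4 libraries low in long transcripts and sarcoma 1268_1270. Col3a1, a fibrillar collagen, rose by 10.23 ± 1.18 (adjusted p = 0.000427), from 0.486 ± 0.707 to 642 ± 374 CPM. Of 14730 genes tested, 662 were called higher and 8 lower in sarcomas, all by at least 2-fold, and 480 of the 662 had a marrow mean under 1 CPM. The groups did not overlap for 652 genes higher and 22 lower, where chance gives 0.14% of genes in each direction. The 22 lower genes are thus near the share that chance gives, and the 652 higher genes are far above it. Sarcoma 1268_1270 held the highest of the 4 values for 584 of the 662 genes. Without it 170 genes were called, all higher, of which 163 were among the 662. Without the 4 libraries low in long transcripts 300 were higher and 3 lower, with 273 of the 662 called again, and without sarcoma 1268_1270 as well 62 were called, all higher. With length and GC offsets on all samples 782 were higher and 18 lower, with 642 of the 662 called again. With the mouse as a block, where mice 1267 and 2721 alone inform the contrast, edgeR called 0 genes (1611 at an unadjusted p under 0.05), and the 114 called from those 2 mice alone were 81 higher and 33 lower. Other tools without the block called partly other genes: DESeq2 called 767 higher, 334 of them among the 662, and 100 lower, and limma-voom 891 higher, 517 of them among the 662, and 21 lower. Scaling to pan-leukocyte genes moved the median of all genes to 1.83 log2 units, from 0.07, and called 6584 higher and 9 lower. This scaling raises sarcoma 1268_1270 most, whose pan-leukocyte list mean was 5.39 log2 CPM. That mean was 9.09, 8.27 and 8.55 in the sarcomas of mice 948, 1267 and 2721, and 8.85 on average in marrow.

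**Figure D2:**
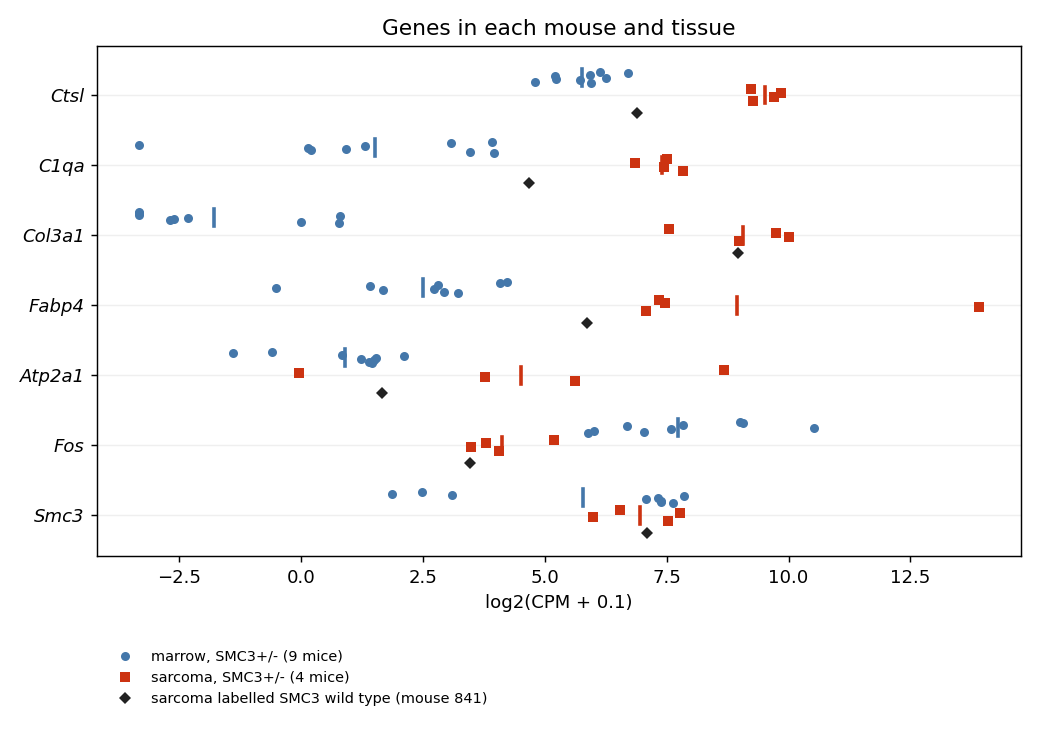
Levels of Ctsl, C1qa, Col3a1, Fabp4, Atp2a1, Fos and Smc3 as log2(CPM + 0.1), with 1 point per mouse and tissue and bars for the group means. Ctsl reaches 603 to 919.9 CPM in the SMC3+/- sarcomas and 27.8 to 104 CPM in marrow.

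Among the genes with the largest fold changes, most of the signal came from sarcoma 1268_1270. Cidec and Plin1, which coat lipid droplets, reached 4868 and 1999 CPM there, against 0.634 to 8.36 and 0.490 to 1.58 CPM in the other 3 sarcomas, and had 4 and 1 counts over all marrows. Sncg, a synuclein also found in fat cells, reached 1729 CPM against 0.663 to 2.22 CPM in the other 3. Gnai1, a G protein subunit, reached 599.5 CPM. Tusc5, a fat-cell membrane protein, reached 445 CPM, and Adh1, an alcohol dehydrogenase, 178 CPM. Each of these 3 stayed under 8 CPM in the other sarcomas. Adh1 had 0 counts over the 9 marrows, where 3 counts would be 0.0146 CPM. Scn7a, a sodium channel, and Sparcl1, a matrix glycoprotein, were present in all 4 sarcomas, at 6.08 to 272 and 5.81 to 363 CPM, with 1 and 3 counts over all marrows. The calls of Plin1, Sncg and Gnai1 were lost without 1 marrow library (779, 779 and 919), and that of Sncg also without sarcoma 1268_1270. Of 51 called genes named here, 26 lost the call when some mouse was left out, 23 of them without sarcoma 1268_1270. None of the 42 with a value was called with the mouse as a block over all mice, and 0 reversed direction. In the blocked fit of mice 1267 and 2721 alone 34 of 49 lost the call, while Ctsl, C1qa, C1qc, Col3a1 and Fos were among those that kept it. DESeq2 did not call 17 of the 51 (Sparc, Lum, Kdr, Rgs5, Cidec, Plin1, Cfd, Fabp4, Scn7a, Sncg, Adh1, Gnai1, Tusc5, Acp5, Adipoq, Cyp2e1 and Trf). Limma-voom did not call 9 (Tnnc2, Atp2a1, Cidec, Cfd, Arg1, Acp5, Adipoq, Cyp2e1 and Trf). Of 48 with a value without the 4 libraries low in long transcripts 17 lost the call, 34 without sarcoma 1268_1270 as well and 30 without marrow 1267 instead. With length and GC offsets on all samples 1 of the 51, Pf4, lost it.

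Fibroblast and matrix genes rose together, with 21 of 26 members higher, 0 lower and 5 not called (23 higher adjusted over the list alone, camera adjusted p = 5.57e-25, adjusted p = 0.0694 with an estimated correlation). Besides Col3a1, Sparc, a collagen-binding glycoprotein, rose by 10.02 ± 1.17 and by 7.25 without sarcoma 1268_1270, its level being 147, 536 and 234 CPM in mice 948, 1267 and 2721 and 6702 CPM in 1268_1270. Mfap5, a microfibril protein, rose by 9.63 ± 1.11 to 28.9 ± 14.3 CPM, with all of its 7 marrow counts in marrow 3332. Lum, a small proteoglycan, had 6.35 to 243 CPM in sarcomas and 2 counts over all marrows. Without the 4 libraries low in long transcripts 18 members were called, and 11 without sarcoma 1268_1270 as well. Of 29 matrix proteases and their inhibitors 12 rose (17 higher and 2 lower adjusted over the list alone, camera adjusted p = 8.17e-08, adjusted p = 0.061 with an estimated correlation, 0.0895 with the mouse as a block and 0.0641 in mice 1267 and 2721 alone). Beyond Ctsl they held Mmp3, a stromelysin, which rose by 8.78 ± 1.06 to 14.8 ± 4.85 CPM, with 7 of its 8 marrow counts in marrow 919. Lox, a collagen cross-linking oxidase, rose by 7.34 ± 1.07, and by 6.71 without sarcoma 1268_1270. Of these members 10 were called without the 4 libraries and 9 without sarcoma 1268_1270 as well.

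Vessel genes were higher too. Of 21 endothelial genes 8 rose (16 adjusted over the list alone, camera adjusted p = 3.41e-17, adjusted p = 0.061 with an estimated correlation). Esam, an endothelial adhesion molecule, rose by 7.40 ± 1.20 to 14.5 ± 17.6 CPM, with 8.31 without marrow 1103 and 6.01 without sarcoma 1268_1270. Kdr, a VEGF receptor, rose by 7.35 ± 1.40, with 8.75 without marrow 779, and lost the call without sarcoma 1268_1270 (4.76). Of 13 pericyte and smooth muscle genes 7 rose (13 adjusted over the list alone, camera adjusted p = 1.79e-13, adjusted p = 0.0694 with an estimated correlation). Among them Rgs5, a pericyte marker, rose by 8.09 ± 1.19 (6.11 without sarcoma 1268_1270, 8.71 without marrow 2721) and Myl9, a smooth muscle myosin light chain, by 8.81 ± 1.24 (6.94 and, without marrow 3332, 9.54). Without the 4 libraries and sarcoma 1268_1270, 0 members of either list were called by edgeR, while camera called both. Of 16 angiogenesis genes Pdgfa alone was called (7 adjusted over the list alone, camera adjusted p = 3.93e-06, adjusted p = 0.17 with an estimated correlation). Pdgfa, a growth factor for mesenchymal cells, rose by 6.15 ± 1.37, with 7.18 without marrow 949, and lost the call without sarcoma 1268_1270 (5.05).

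Muscle and fat genes differed widely between tumours. Of 16 skeletal muscle genes 9 rose (14 adjusted over the list alone, camera adjusted p = 1.71e-07, adjusted p = 0.264 with an estimated correlation, 0.459 with the mouse as a block and 0.0817 with the mouse as a random effect). Atp2a1, the calcium pump of fast muscle, rose by 5.63 ± 0.98 and by 3.37 without sarcoma 948, with 408 CPM in mouse 948, 0.865 in 1267, 13.6 in 1268_1270 and 49.0 in 2721. Tnnc2, a fast troponin, rose by 8.69 ± 1.46 and by 6.22 without sarcoma 948, from 245 CPM there to 0.0288 CPM in mouse 1267. Of 12 adipocyte genes 11 rose (12 adjusted over the list alone, camera adjusted p = 5.74e-06, adjusted p = 0.324 with an estimated correlation). Fabp4, a fatty acid carrier, had 162, 176 and 135 CPM in mice 948, 1267 and 2721 and 15260.0 CPM in 1268_1270. It rose by 8.97 ± 1.30 and by 4.21 without that sarcoma. Cfd, the adipokine adipsin, rose by 9.94 ± 1.38 and by 5.96 without it. Without the 4 libraries low in long transcripts 0 muscle and 3 adipocyte genes were called, and 0 and 1 without sarcoma 1268_1270 as well.

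**Figure D3:**
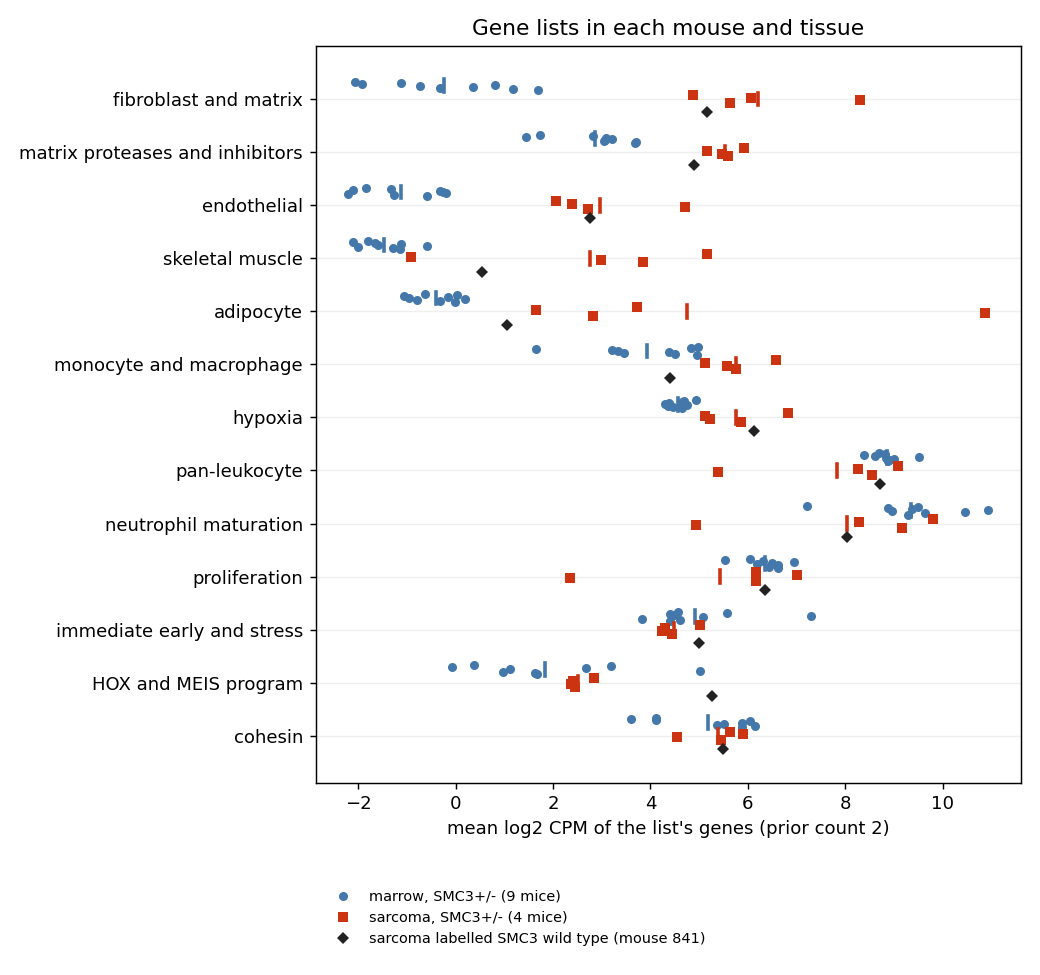
Mean log2 CPM of 13 gene lists, with 1 point per mouse and tissue and vertical bars for the group means. The fibroblast and matrix list averages 6.21 in the SMC3+/- sarcomas and -0.24 in marrow, relative to library totals.

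Of 26 monocyte and macrophage genes 6 rose, 0 fell and 20 were not called (10 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00811, adjusted p = 0.497 with an estimated correlation, and 0.600 with the mouse as a block). Beside C1qa and C1qc, Apoe, a lipid carrier of macrophages and liver, rose by 3.08 ± 0.59 and lost the call without sarcoma 1268_1270 (2.06, adjusted p = 0.0919). Folr2, a folate receptor of resident macrophages, rose by 6.28 ± 1.27 (6.99 without marrow 737) and lost the call without sarcoma 1268_1270 (5.29). The list's own call was lost without marrow 919 (adjusted p = 0.0792) or sarcoma 948 (0.154), with DESeq2 (0.0743) and in mice 1267 and 2721 alone (0.539). Its range over alternatives was 0.000304 to 0.600. Of 11 listed lymphoid stroma genes 4 passed the count filter, which genes near 0 in marrow pass only through the sarcomas. All 4 rose, 4 also adjusted over the list alone (camera adjusted p = 1.30e-06, adjusted p = 0.061 with an estimated correlation). They included Cxcl13, a chemokine of lymphoid follicles, at 7.30 ± 6.51 CPM with 1 count over all marrows, and Il33, an alarmin of stromal cells (6.15 ± 1.34; 7.07 without marrow 1103; call lost without sarcoma 1268_1270, 5.70). Of 20 hypoxia genes 3 rose (4 adjusted over the list alone, camera adjusted p = 0.0232, adjusted p = 0.415 with an estimated correlation, and 0.183 with the mouse as a block). Bnip3, a mitophagy receptor (2.89 ± 0.66), P4ha2, a collagen hydroxylase (7.04 ± 1.42), and Adm, a vasodilating peptide (5.71 ± 1.33), all lost the call without sarcoma 1268_1270 (2.07, 6.30 and 5.58). Of 28 marrow counts of P4ha2 26 lay in marrow 1103, and the rise of Adm was 6.95 without marrow 949. The hypoxia list lost its call without marrow 919 (adjusted p = 0.0535), sarcoma 948 (0.479) or sarcoma 2721 (0.0951), with the first tumour of a mouse only (0.0750) and in mice 1267 and 2721 alone (0.178). Its range over alternatives was 3.86e-06 to 0.479.

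The number of genes lower in sarcomas depended on the tool, with 8 called by edgeR, 21 by limma-voom, 38 by limma-voom with the mouse as a random effect and 100 by DESeq2. Fos, an immediate early transcription factor, fell by 4.34 ± 1.00 (log2, adjusted p = 0.0211), from 366 ± 451 CPM in marrow to 19.4 ± 11.5 CPM in sarcomas, and lost the call without sarcoma 1267, 1268_1270 or 2721; without marrow 949 the change was -3.57. Zfp36, which speeds decay of cytokine messages, fell by 2.67 ± 0.69 (adjusted p = 0.0411; 362 ± 403 to 59.9 ± 18.4 CPM). E2f2, a cell cycle transcription factor, fell by 2.04 ± 0.54 (adjusted p = 0.0425; 177 ± 63.3 to 46.4 ± 32.5 CPM), and Tgfbi, a secreted matrix protein, by 1.73 ± 0.39 (adjusted p = 0.0185; 374 ± 118 to 122 ± 56.3 CPM). The call of Zfp36 was lost without any of the 4 sarcomas or without marrow 779, 919, 1103, 2721 or 3332, and its change was -1.93 without marrow 949. That of E2f2 was lost without sarcoma 1267, 1268_1270 or 2721 or any marrow but 782. That of Tgfbi was lost without sarcoma 1268_1270 or 2721. Scaling to pan-leukocyte genes moved Zfp36 to -0.40 and Tgfbi to -0.12 and ended both calls. None of the 4 was called without the 4 libraries low in long transcripts, although each of these genes kept the call with length and GC offsets. The immediate early and stress list was lower by camera, with Fos and Zfp36 lower, Cyr61 higher and 21 of 24 members not called (1 higher and 3 lower adjusted over the list alone, adjusted p = 5.42e-05, adjusted p = 0.324 with an estimated correlation). Its median was -1.51 and turned to 0.18 with pan-leukocyte scaling, and fry did not call the list (adjusted p = 0.348). Cyr61, a matricellular protein, rose by 5.94 ± 1.29 (7.24 without marrow 2721) and lost the call without sarcoma 1268_1270 (5.27). Junb had a change of -2.29 that did not pass (adjusted p = 0.0974).

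Lists of blood cells and of proliferation were lower in sarcomas by camera with hardly any single gene called, relative to the other genes, whose median pan-leukocyte scaling moved to 1.83. Sarcoma 1268_1270 stood apart in the means of several of these lists, with 5.39 log2 CPM for the pan-leukocyte, 4.93 for the neutrophil maturation and 2.34 for the proliferation list. In mice 948, 1267 and 2721 they were 9.09, 8.27 and 8.55, then 9.80, 8.28 and 9.16, then 6.16, 7.01 and 6.17, in or near the marrow ranges of 8.38 to 9.52, 7.22 to 10.94 and 5.52 to 6.95. The pan-leukocyte list had a median of -0.73 with 0 of 20 members called (camera adjusted p = 5.51e-10, adjusted p = 0.264 with an estimated correlation), and its member Laptm5, a lysosomal protein of blood cells, had a change of -1.01 (adjusted p = 0.287). Of 23 neutrophil maturation genes 0 were called (median -0.85, camera adjusted p = 1.35e-07, adjusted p = 0.324 with an estimated correlation), with Mmp9, gelatinase B, at -2.66 (adjusted p = 0.202; -3.96 without sarcoma 2721). Of 10 mast cell, basophil and eosinophil genes 0 were called, and 1 was lower adjusted over the list alone (median -2.25, camera adjusted p = 0.000244, adjusted p = 0.17 with an estimated correlation), with Prss34, a basophil protease, at -7.69 (adjusted p = 0.057; -6.90 without marrow 1103), found at 0.671 CPM in sarcoma 2721 and at 0.0 in the other 3. The call of this list was lost with DESeq2 (0.0516) and with no count filter (0.112). Of 26 erythroid genes 0 were called (median -1.78, turning to 0.21 with pan-leukocyte scaling, camera adjusted p = 0.00418, adjusted p = 0.658 with an estimated correlation), with Slc4a1, the red cell anion exchanger, at -5.85 (adjusted p = 0.124; -4.91 without marrow 1103). The call of the erythroid list was lost without marrow 1103 (0.0997), with a stricter count filter (0.170) or with the tumour of mouse 841 added (0.0503). Of 25 T and NK cell genes 0 were called (median -1.16, turning to 1.08, camera adjusted p = 0.0147, adjusted p = 0.537 with an estimated correlation). The call of the T and NK cell list was lost without marrow 737 (0.0511), sarcoma 2721 (0.0938) or the 4 libraries (0.138; 0.0558 without sarcoma 1268_1270 as well, 0.160 without marrow 1267 instead), and in mice 1267 and 2721 alone (0.0865). The 13 primary granule genes (median -0.15, turning to 0.26, camera adjusted p = 0.00325, adjusted p = 0.415 with an estimated correlation, and 0.600 with the mouse as a block) had 0 calls, with Mpo, myeloperoxidase, at -0.93 (adjusted p = 0.882; -2.98 without sarcoma 1267). The call of this list was lost without sarcoma 1268_1270 (0.566), also with the 4 libraries left out (0.536), without the 4 and marrow 1267 (0.117), with length and GC offsets (0.402), with DESeq2 (0.172) and in mice 1267 and 2721 alone (0.558). The 30 proliferation genes (median -0.55, turning to 0.01, camera adjusted p = 6.54e-10, adjusted p = 0.324 with an estimated correlation, and 0.0765 with the mouse as a block) had 0 calls, with Mcm2, a replicative helicase subunit, at -0.87 (adjusted p = 0.481; -1.47 without sarcoma 1267). Apart from the 1 mast cell list gene, 0 members of these 7 lists were called adjusted over the list alone. Fry called none of the 7, with adjusted p from 0.0911 for the mast cell list to 0.700 for the erythroid list.

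Homing and adhesion genes were lower by camera (28 measured, 1 higher and 1 lower adjusted over the list alone, median -0.51 turning to 0.63 with pan-leukocyte scaling, adjusted p = 0.0131, adjusted p = 0.324 with an estimated correlation), although Ackr3, a scavenging receptor for Cxcl12, rose by 7.17 ± 1.21 (5.87 without sarcoma 1268_1270). The call of the homing list was lost without sarcoma 1267 (0.0591) or 1268_1270 (0.0531), without the 4 libraries and sarcoma 1268_1270 (0.0562) or marrow 1267 (0.0516), with tumour libraries as units (0.0568) and with the tumour of mouse 841 added (0.0505). The 26 ribosomal protein genes had 0 calls (0 adjusted over the list alone) and a median of -0.19, turning to 0.58 with pan-leukocyte scaling (camera adjusted p = 0.0195, adjusted p = 0.839 with an estimated correlation). Fry called neither the homing list (adjusted p = 0.64) nor the ribosomal list (0.901). The ribosomal list was called in the opposite direction without the 4 libraries and sarcoma 1268_1270 (adjusted p = 0.0201) or marrow 1267 (0.0318). It had that direction without a call with the mouse as a block (0.701), in mice 1267 and 2721 alone (0.966) and with pan-leukocyte scaling (0.727; range over alternatives 4.96e-05 to 0.966). Its call was lost without the 4 libraries (0.798), with length and GC offsets (0.194), with the first tumour of a mouse only (0.264), with tumour libraries as units (0.0568), with the mouse as a random effect, and without marrow 737 (0.154), 779 (0.153), 782 (0.130) or 1267 (0.0675) or sarcoma 1268_1270 (0.936). Marrow stroma niche genes were higher by camera (9 measured, 1 called, 4 adjusted over the list alone, adjusted p = 0.00113, adjusted p = 0.17 with an estimated correlation, 0.236 with the mouse as a block and 0.0936 in mice 1267 and 2721 alone). The called member was Adipoq, adiponectin, which rose by 11.12 ± 2.12 (12.14 without marrow 779) and lost the call without sarcoma 1268_1270 (4.21). Epithelium and skin genes were higher by camera (8 measured, adjusted p = 0.0312, adjusted p = 0.17 with an estimated correlation), with 1 called, 1 also over the list alone, but had the opposite direction with the mouse as a block (0.763, range over alternatives 2.73e-05 to 0.763) and no call without marrow 3332 (0.0630) or sarcoma 948 (0.173). That call was lost as well with length and GC offsets (0.224), pan-leukocyte scaling (0.0630), a stricter count filter (0.341), tumour libraries as units (0.447), the first tumour only (0.418), the mouse as a random effect (0.615), the tumour of mouse 841 added (0.204), in mice 1267 and 2721 alone (0.0936) and without the 4 libraries and marrow 1267 (0.0827). The called member was Trp63, a factor of basal epithelium, at 1.08 ± 0.387 CPM with 1 count over all marrows.

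For 15 further lists and the cohesin list camera made no call. Ly6a, a stem cell antigen also made by endothelium, rose by 2.72 ± 0.64 among 19 stem and progenitor genes (2 adjusted over the list alone, adjusted p = 0.604; median -0.44, mean 0.04) and lost the call without sarcoma 1268_1270 (2.07). Pf4, a platelet chemokine, rose by 3.40 ± 0.91 among 14 megakaryocyte genes (1, adjusted p = 0.594), a call lost in 9 of the 13 fits that left out a mouse: all sarcomas but 1267, and marrow 737, 779, 782, 919, 949 and 3332. Acp5 and Ctsk, osteoclast enzymes, rose by 2.59 ± 0.61 and 3.78 ± 1.00 among 10 bone and cartilage genes (4 higher and 1 lower, adjusted p = 0.568). Acp5 lost the call without sarcoma 1268_1270 (0.77), and Ctsk without sarcoma 1267, 1268_1270 or 2721 (2.34) or marrow 737, 779, 782, 919, 1103 or 2721. S100b and Pmp22, Schwann cell genes, were called among 8 nerve genes (2, camera adjusted p = 0.104, 0.0464 with pan-leukocyte scaling, fry adjusted p = 0.000264). S100b had 0.403 to 10.2 CPM with 3 counts over all marrows and Pmp22 a rise of 4.35 ± 1.02, and both lost the call without sarcoma 1268_1270. Cyp2e1, a liver cytochrome, and Trf, transferrin, rose by 10.67 ± 1.85 and 3.28 ± 0.83 among 4 liver genes (3, adjusted p = 0.104) and lost the call without sarcoma 1268_1270 (6.94 and 0.32); Trf lost it also without any marrow but 737. The liver list was called higher without marrow 737 (0.0359), 779 (0.0390), 782 (0.0469), 1267 (0.0405) or 2721 (0.0485), without sarcoma 1267 (0.00163) or 2721 (0.0173), with length and GC offsets (0.00276), DESeq2 (8.97e-05), no count filter (0.00178) and with no mouse in both groups (0.0424). Ccl12, a monocyte chemokine, rose by 7.25 ± 1.35 among 21 inflammatory cytokines (2, adjusted p = 0.961; median -0.08, mean 0.54), with 6.40 without sarcoma 948 and 5 counts over all marrows, all in mice 779 and 3332. Arg1, arginase, rose by 6.73 ± 1.34 among 17 checkpoint genes (1, adjusted p = 0.869; median 0.09 with camera pointing down), with 7.61 without marrow 2721, and lost the call without sarcoma 948 (4.48). No member was called, over all genes or over the list alone, for the HOX and MEIS (18 genes, adjusted p = 0.922), dendritic cell and MHC class II (17, 0.869; 0.0480 with the mouse as a block), B cell (16, 0.427; 0.0152 with length and GC offsets and 0.00494 with pan-leukocyte scaling), plasma cell (8, 0.462), glycolysis (16, 0.341; median 0.12 with camera pointing down), interferon (28, 0.719), RAS and MAPK feedback (18, 0.813) or oxidative phosphorylation lists (23, 0.372; 0.00954 without the 4 libraries and marrow 1267). Without sarcoma 948 the glycolysis list was called lower (0.00629). In all 22 of 38 lists were called by camera, 0 with an estimated correlation, 13 with fry, all of them higher, and 14 with the mouse as a block.

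The tumour labelled SMC3 wild type was set beside the 4 SMC3+/- sarcomas. With 1 mouse in that arm, this is a comparison with that mouse and not with its genotype. The Smc3 level of this tumour lay among those of the 4. Genes of the HOX and MEIS list, all homeobox factors but Flt3 and Sox4, were higher in it, 16 of 18 above all 4 SMC3+/- sarcomas, with a median difference of 2.63 log2 units (percentile 100 among random lists) and 1.74 with pan-leukocyte scaling. Hoxa3 had 35.1 CPM against 5.78 ± 0.948 CPM. Monocyte and macrophage genes had a median difference of -1.36 (percentile 0.0), 13 of 26 below all 4, with C1qa at 25.6 CPM against 115 to 228 CPM. Matrix proteases (median -0.74, 11 of 29 below all 4), fibroblast genes (-0.93, 8 of 26), adipocyte genes (-3.38, 5 of 14) and skeletal muscle genes (-2.05, 3 of 20) also lay at percentile 0.0, with Ctsl at 118 CPM against 603 to 919.9 CPM and Mmp3 at 1.93 CPM against 11.3 to 21.9 CPM. Single tumours of mouse 948 had 285 CPM of Ctsl (tumour 1) and 3.45 CPM of Mmp3 (tumour 2). The list mean of mouse 841 lay within the SMC3+/- range for fibroblast genes (5.16 against 4.87 to 8.30 log2 CPM) and muscle genes (0.54 against -0.92 to 5.16). For adipocyte genes it was 1.06, against 3.72, 1.64 and 2.81 in mice 948, 1267 and 2721 and 10.87 in 1268_1270. Oxidative phosphorylation genes (-0.66, 14 of 23, percentile 0.0), T and NK cell genes (-2.18, 17 of 26, percentile 0.09) and B cell genes (-2.12, 9 of 18, percentile 0.14) were low as well. The oxidative phosphorylation mean of 6.85 log2 CPM in mouse 841 was above the 6.39 of tumour 2 of mouse 948, whose tumour 1 had 8.54. Pan-leukocyte, primary granule, proliferation and homing genes lay at percentile 100, with medians of 0.79, 1.25, 0.94 and 0.85, but few members lay above all 4 mice (5 of 20, 1 of 13, 1 of 30 and 6 of 28). The low values of sarcoma 1268_1270 weighed on these, the proliferation mean being 6.36 log2 CPM in mouse 841 against 6.16, 7.01, 6.17 and, in 1268_1270, 2.34. Scaling to pan-leukocyte genes, which shifted all genes by -0.89, left -0.10, 0.36, 0.05 and -0.04. Hypoxia genes (0.37, percentile 99.4) and cohesin genes (0.12, percentile 84.8) turned to -0.52 and -0.77 with that scaling.

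Single genes of that tumour stood outside the SMC3+/- range in both directions. Above it were S1pr3, a sphingosine-1-phosphate receptor (51.2 against 7.55 ± 2.44 CPM), H2-T10 (40.9 against 7.05 ± 1.74 CPM), Rpgrip1 (185 against 27.5 ± 13.8 CPM), Sh2d5 (165 against 21.4 ± 17.7 CPM) and Ikzf2, a zinc finger factor of the Ikaros family (168 against 11.7 ± 16.9 CPM). Below it were Nr1h3, the oxysterol receptor LXR alpha (0.176 against 38.5 ± 50.5 CPM), Igj, the immunoglobulin J chain (0.351 against 85.2 ± 59.9 CPM), Penk, an opioid precursor (0.439 against 269 ± 499 CPM), Ces1d, a carboxylesterase (0.176 against 293 ± 497 CPM), Hebp1 (0.439 against 65.4 ± 98.5 CPM) and Orm1, an acute phase protein (0.966 against 53.9 ± 57.5 CPM). Single SMC3+/- tumours reached low values of Igj, 0.512 CPM in tumour 2 of mouse 2721 and 3.61 CPM in tumour 2 of mouse 948, so this gene did not set the tumour of mouse 841 apart from every other tumour. In its library 3 counts were 0.263 CPM, so Nr1h3 and Ces1d were at the limit of its depth. Of 9880 genes 877 lay above and 1551 below the range of the 4 mice, 24.6% where chance gives 40%, and 65 and 148 lay outside by more than 1 log2 unit. With the lone tumour assumed to vary like the others, edgeR called 0 of 17762 genes (236 at an unadjusted p under 0.05), DESeq2 called 68 (8 higher, 60 lower), and edgeR without sarcoma 1268_1270 called 1, Aldh1a3, a retinaldehyde dehydrogenase. Aldh1a3 had 253 CPM in mouse 841 against 1.01 to 16.9 CPM in the 4 SMC3+/- sarcomas, and was named after its values were seen. The difference was 7.71 log2 units without sarcoma 1268_1270, given as a size only because the lone tumour has no spread of its own.

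Tumours of the same mouse were compared over 14730 genes, each centred on the 6 SMC3+/- tumours. The tumours of mouse 2721 correlated at r = 0.64 and those of mouse 948, of which tumour 1 was low in long transcripts, at r = -0.21, while pairs from different mice had r between -0.48 and 0.01. The mean r of 0.21 was not called (exact permutation test, one-sided, p = 0.0667 over 45 arrangements, smallest possible 0.022), and genes are not independent replicates. Sarcoma and marrow of the same mouse had a higher r than those of different mice by 0.27, again not called (exact permutation test, one-sided, p = 0.0556 over 72 arrangements, smallest possible 0.014). Over the 1000 most variable genes both passed, with exact permutation p = 0.0222 and p = 0.0278, although the tumours of mouse 948 had r = -0.046. With Spearman correlation neither passed, with exact permutation p = 0.0889 and p = 0.0556.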

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

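The count of list calls over other groupings of the mice was planned; the other tests in this part were chosen after the results were seen. A value stood far from the rest of its group in 35 of 214 groups of 4 to 9 samples. Independent normal values would give about 1 in 20 groups, or 11 here. Several flagged genes had counts in only 1 sample of the group, and genes were named partly for large fold changes. The 35 can therefore not be set against that 11 as a test of chance.

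Most genes called were higher in sarcomas. With the samples taken as independent, 2 of 100 splits of the 13 samples into 4 and 9 called as many as the real 670, the real one included. Of 100 splits that parted the tissues of mice 1267 and 2721 as the real one does, 1 did (highest other 0). Such splits cannot hold marrow 737, 779 and 782 together in the group of 4, so that 0 is partly preset. Other splits thus rarely reached the real count, but with the mouse as a block 0 genes were called. Only mice 1267 and 2721 inform the tissue contrast of the blocked fit. Its 0 therefore cannot tell a lack of difference from a lack of samples. The highest split of the first kind called 4116 genes, parting marrow 737, 779, 782 and 1267 from the rest, which points to a structure of the samples along the loss of long transcripts. For lists 3 of 100 splits called as many as the real 22 (highest other 24) and 2 of 100 of those parting the 2 mice, but all 99 other splits called some, with a median of 12, and 0 were called with an estimated correlation, so single list calls carry little weight. The libraries low in long transcripts are argued against as the whole cause, since 273 of 662 higher genes were called again without them, whereas normalization stays open, since 0 of 4 other scalings lowered the median of all genes by over 0.1 log2 units, as a scaling that adds lower calls would. A candidate explanation is host tissue in the tumours, with 51.5% of the members of 11 non-blood lists called higher against 3.8% for 11 blood lists. The shares were only 22.9% against 0.9% without sarcoma 1268_1270 and 10.2% against 0.9% without the 4 libraries as well, under the 30% set for it. Non-blood genes near 0 in marrow passed the count filter only through the sarcomas, so these shares are partly preset. Expression by the leukaemia cells themselves, as a difference between tissues, was not tested.

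Long transcripts were low in marrow 737, 779 and 782 and in tumour 1 of mouse 948. Depth alone is argued against, since 9 libraries with fewer counts than the deepest of the 4 had slopes on log2 length above -0.5. GC content as the whole cause is argued against as well, since the slope stayed at -0.653 or lower with GC in the regression. The 4 libraries also had low GC slopes in it, at -0.607, -0.510, -0.579 and -0.858 log2 units per 10 points, against -0.032 to 0.196 in the 12 others. Counts that no longer scale with length, for which slopes of -1 to -0.5 were predicted, stay open: the slope nearest 0 on either side of the median length was -0.333, those above that length were -1.55, -1.50 and -1.49 in marrow 737, 779 and 782, but with libraries centred on their mean and no GC term, the version computed first, these were -1.14, -1.12 and -1.10, past -1 by less than the spread of the 12 other libraries (-0.216 to 0.548), and that of tumour 1 of mouse 948 was -0.246, just past the bound of -0.25 set against this explanation. Partly degraded RNA read from the 3' end may give such a slope and was not tested, as positions of reads along transcripts were not used here. No biological explanation was tested.

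Fos and Zfp36 were lower in sarcomas. Loss of long transcripts is argued against, since without the 4 libraries the log2 change was -3.54 ± 1.17 for Fos and, nearest to 0, -2.43 ± 0.78 for Zfp36, after -4.34 ± 1.00 and -2.67 ± 0.69 with them, although with fewer samples and a larger SE neither was called (edgeR adjusted p = 0.178 and 0.167). Handling of marrow before lysis cannot be told apart from tissue, for the 2 genes or for the whole immediate early list, because 0 samples of either tissue were lysed by the route of the other. For the list 6 of 9 marrows lay inside or below the sarcoma range, but 3 of 9 without sarcoma 948, so the count decides nothing. A difference between tissues stays open, untested.

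The other values far from their group were these. Marrow 1267 had 22.3% of its counts in its top 10 genes and 6.4% in Rn45s, a ribosomal RNA precursor. Marrow 1103 had 0.173% haemoglobin counts, P4ha2 at 0.843 CPM and Cyp2e1 at 0.908 CPM. Tumour 1 of mouse 948 had 16.4% of counts in its top 10 genes and a GC slope of -0.858 log2 units per 10 points. Marrow 949 had a B cell list mean of 4.61 and an immediate early list mean of 7.29 log2 CPM, with Ctsk at 0.0 CPM. In marrow 3332 Mfap5 was at 0.229, Sparcl1 at 0.0982 and Tusc5 at 0.0982 CPM. In marrow 919 Mmp3 was at 0.163, Cxcl13 at 0.0232, Gnai1 at 0.0697 and Trp63 at 0.0232 CPM. Marrow 782 had C1qc at 0.0 and Laptm5 at 333 CPM. In marrow 779 Kdr was at 1.02, Plin1 at 0.0930, Scn7a at 0.0930, Sncg at 0.186 and S100b at 0.279 CPM. Sarcoma 948 had a HOX and MEIS list mean of 2.85 log2 CPM. Sarcoma 2721 had Prss34 at 0.671 CPM. Sarcoma 1267 had Adm at 1.07 CPM. Sarcoma 1268_1270 had Kdr at 78.3, Plin1 at 1999, Fabp4 at 15260.0, Laptm5 at 93.3, Scn7a at 272, Sncg at 1729, Gnai1 at 599.5 and Tusc5 at 445 CPM.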

How the results depend on the processing

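The removals of libraries low in long transcripts and the length and GC offsets were chosen after the data were seen; the other alternatives were planned. Where a value changed and no cause is given, the cause was not tested. From 670 genes called, 4 other scalings, other tools and filters and single mice left out gave these changes. Pan-leukocyte scaling, which moves the median of all genes, gave 6593, and no count filter, which tests more genes, gave 1368. Limma-voom gave 912, and 1009 on single tumour libraries with the mouse as a random effect. With each mouse left out 170 to 765 were called, the lowest without sarcoma 1268_1270. With the mouse as a replicate block over 15 libraries 0 were called, and 114 from mice 1267 and 2721 alone, which leave 2 pairs. Without the 4 libraries low in long transcripts 303 were called, 62 without sarcoma 1268_1270 as well and 166 without marrow 1267 instead. With length and GC offsets on all samples 800 were called. Lists called went from 22 to 14 in each blocked fit, 0 with an estimated correlation and 13, all higher, with fry. The epithelium and skin list reversed with the block (adjusted p = 0.763), and the ribosomal protein list with pan-leukocyte scaling (0.727), the block (0.701), the pair of mice (0.966), without 5 libraries (0.0201) and without the 4 and marrow 1267 (0.0318); the block changed other list and gene calls only as given beside them. For the tumour labelled SMC3 wild type, DESeq2 called 68 genes against 0, edgeR 0 to 1 (Aldh1a3) with each mouse left out, and 1 without tumour 1 of mouse 948 and sarcoma 1268_1270. Its Smc3 difference moved to -0.74 with pan-leukocyte scaling, with an SD of 1.31 between the SMC3+/- mice. With the 1000 most variable genes the mean correlation of same-mouse tumours was 0.30, and sarcoma and marrow of the same mouse exceeded those of different mice by 0.37 in r, and both then passed the test. With Spearman correlation neither passed. Over all alternatives the 51 called genes named kept their call in 1391 values and lost it in 284 in the same direction, and 5 of the 11 others gained one in 16. The 22 called lists kept it in 690, lost it in 95 and reversed in 6, and 7 of the 16 others gained one in 21. Scaling by spike-in totals was not run, since the table holds 0 spike-in rows. In mouse 841, with 9797201 counts, 3 counts are 0.263 CPM, which limits what can be said of genes near 0 there.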

Other observations

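Nothing in this part was tested, and the genes, mice and lists in it were chosen after their values were seen. Genes of the HOX and MEIS list were high in the tumour of mouse 841, labelled SMC3 wild type and with an Smc3 level among those of the SMC3+/- sarcomas, and in 1 SMC3+/- marrow, that of mouse 1103. Their list mean was 5.26 and 5.01 log2 CPM in these samples and -0.07 to 3.19 in the other 12. Hoxa3 had 35.1 and 34.4 CPM, Hoxb3 52.7 and 50.5 CPM, Hoxb6 73.1 and 47.0 CPM, and Meis1 39.7 and 37.3 CPM in mouse 841 and marrow 1103, whereas Hoxa3 stayed at or under 9.99 CPM in every other sample. Hoxa11, a posterior HOX gene, had 222 CPM in mouse 841 and 94.2 CPM in marrow 1103, but also 102 CPM in marrow 782 and 82.2 CPM in sarcoma 1267. Some members were highest elsewhere: Hoxb2 in marrow 779 (39.4 CPM against 21.7 and 31.0) and Hoxa10 in marrow 782 (302.7 CPM against 295.4 and 177.1). Hoxa9 had 156 CPM in marrow 1103, under the 180 of marrow 3332 and 187.5 of sarcoma 2721.

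The tumours differed in the tissues whose genes they held, and in hypoxia genes. Adipocyte list genes took 7.76% of the counts of sarcoma 1268_1270 against 0.0459% to 0.0882% in the other 5 SMC3+/- tumours, while its pan-leukocyte list took 0.0977% against 0.858% to 1.25%. Skeletal muscle genes took 0.281% in tumour 1 of mouse 948 and 0.103% in tumour 2 of mouse 2721, and at most 0.0304% in the other 4. Hypoxia genes took 0.706% in tumour 2 of mouse 948 and 0.288% in its tumour 1, against 0.178% to 0.253% in the other 4. The value of tumour 1 was exceeded by the tumour of mouse 841 (0.334%) and by marrow 782 (0.314%) and 737 (0.294%). Erythroid genes averaged 5.32 log2 CPM in marrow 1103 and 4.73 in marrow 949, against at most 2.97 in the other 7 marrows.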
